A study of Mus musculus with 9 samples.

How the data were processed

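The series measured RNA from cDC1 of mouse lymph nodes near the pancreas in 9 libraries, 3 each from the Healthy, PanIN and Tumor stages named in the labels. Per the labels' protocols, RNA was extracted with a column micro kit and libraries were made with a directional (stranded) kit. The authors deposited estimated counts and TPM per transcript, quantified with Salmon on mm10, per the submitters' processing notes; the version and settings are not given in the sources used here. The names of the deposited files mention sailfish, another quantifier, so which tool made the values is open. The deposited estimated counts are not normalized and need not be whole: 13.4% to 15.9% of the values above 0 in each library were exactly whole as written, with no tolerance. The deposited TPM sum to 1000000 in each library. Because transcript quantification splits reads between similar transcripts by a model, values of paralogs and pseudogenes are uncertain, and whether the strand was used in quantification is not given in the sources used here.

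Of the 136288 transcripts, 136176 were matched by identifier to the GENCODE M21 annotation of GRCm38, and 112 were not and were left out; matched transcripts held at least 99.963% of the counts of each library. Counts were summed to 53458 genes and rounded to whole numbers. Genes passing filterByExpr with its defaults (minimum count 10, minimum total 15) numbered 24133. Tests used edgeR 4.0.16 in R 4.3.3, with TMM factors from 0.83 to 1.19, and one quasi-likelihood fit over all 9 libraries with group as the only term. The 3 pairwise contrasts and a test of any difference among stages were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The common biological coefficient of variation was 56.5%. Levels are CPM with TMM factors. Depths ran from 32150281 to 68934430 counts per library.

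Before the data were examined, the groups, the design, 41 gene lists, most alternatives and the rule for named genes were fixed. The rule took, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among called genes whose 3 libraries of one group all lay beyond those of the other and whose mean was at least 1 log2 CPM. Where fewer than 5 passed it added the 5 with the smallest p in each direction, said not to pass; it also took up to 4 members per list and a fixed set of dendritic cell and apoptosis genes. Predicted genes and receptor segments were left out. Lists were tested member by member with adjustment over the list alone, with camera (limma 3.58.1; preset correlation 0.01, and estimated), with fry, and with an exact permutation test of the list mean (F statistic, no direction) over 1680 assignments. With 3 libraries against 3 an exact permutation test cannot give p below 0.1.

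The tests were tried on simulated counts with 200 changed genes, all with a mean of at least 1 log2 CPM. Genes were drawn independently, with the same dispersion per gene in every group. In Tumor against Healthy, 14.9% of 2-fold, 70.1% of 4-fold and 89.4% of 8-fold changes were recovered, so most 2-fold changes would be missed at this size and spread. In PanIN against Healthy these were 4.5%, 68.7% and 83.3%, and in Tumor against PanIN 6%, 71.6% and 87.9%. Unchanged genes called numbered 9 in Tumor against Healthy, 3 in PanIN against Healthy and 7 in Tumor against PanIN. These shares are for the simulated setting. A gene not called in the real libraries may still differ by 4-fold or more.

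Alternatives covered DESeq2 1.42.0, RLE factors, other filters, limma-voom with sample weights, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), counts rebuilt from TPM, a surrogate variable (sva 3.50.0), fewer libraries, and a term for the title code shared by 3 libraries. Leaving out Healthy 2 and Healthy 3 together, protein-coding genes alone, a term for Ccr7 and Fscn1, a term for 7SL RNA and the permutation of list means were chosen after seeing the data. Labels carry no replicate numbers, so no libraries were paired. Tables were made with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9. Some genes covered by the rule for named genes are not reported here.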

Results

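RNA was sequenced from conventional type 1 dendritic cells (cDC1), the dendritic cells specialised in presenting captured antigen to cytotoxic T cells, of mouse lymph nodes next to the pancreas. The series title names KPC, a mouse model of pancreatic cancer. The 9 libraries fell into 3 groups of 3 by the stage of the drained pancreas: Healthy, PanIN (pancreatic intraepithelial neoplasia, the precursor lesion) and Tumor. Libraries held 32150281, 45948090 and 68934430 estimated counts in Healthy, 35424553, 36894434 and 43144289 in PanIN, and 41430103, 46041617 and 36465371 in Tumor. The labels do not say whether the libraries came from separate animals or from pools, so the p-values measure only the spread between these libraries, which may be technical. The genes that define cDC1 were abundant in every library: Xcr1 stood at 601 ± 419 CPM (SD, n = 3) in Healthy, 509 ± 182 in PanIN and 418 ± 188 in Tumor, and Irf8 at 1970 ± 1210, 2040 ± 520 and 1830 ± 487 CPM.

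The Healthy libraries differed among themselves. Ccr7, the chemokine receptor that brings mature dendritic cells to lymph nodes, stood at 57.2 CPM in Healthy 2, against 1270 in Healthy 1 and 419 in Healthy 3. Fscn1, an actin-bundling protein of mature dendritic cells, stood at 145 CPM in Healthy 2, against 3490 and 1600. In Healthy 3 the 7SL RNA gene Rn7s1 took 1.78% of counts and mitochondrial ribosomal RNA 2.77%, where the other 8 libraries held at most 0.76% and 1.26%. The next highest were Healthy 1, at those values, and PanIN 1, at 0.56% and 1.03%. The first principal component, with 28.3% of the variance, placed Healthy 3 and Healthy 2 at its ends. No pair of libraries agreed within sampling noise.

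**Figure D1:**
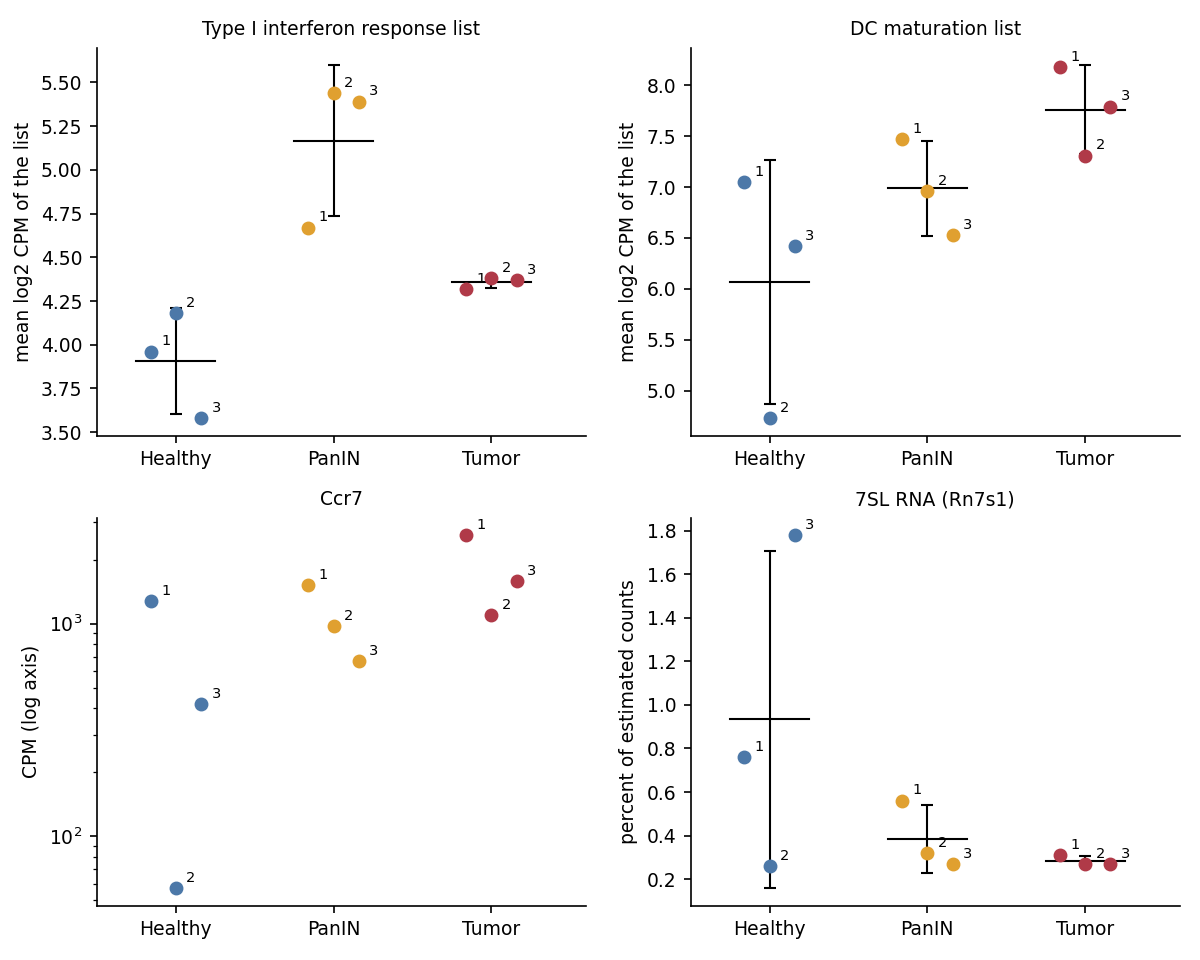
Values per library in the 3 groups, numbered by replicate: mean log2 CPM over the type I interferon list (42 genes) and over the maturation list (30 genes), Ccr7 in CPM on a log axis, and the percent of estimated counts on 7SL RNA. Lines and bars are means and SD (n = 3), not drawn for Ccr7; PanIN libraries lie above the other groups for the interferon list, and Healthy 2 lies lowest for Ccr7 at 57.2 CPM.

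The comparison of PanIN with Healthy asked how cDC1 expression differed where the node drained precursor lesions. The clearest group of genes was the type I interferon response, the antiviral genes that cells switch on when they sense interferon. All 42 measured members had a positive log2 fold change, with a median of 1.17, and 26 rose when adjusted over the list alone. Isg15, a ubiquitin-like modifier, stood at 43.6 ± 4.67 CPM (SD, n = 3) in PanIN against 15 ± 4.33 in Healthy. Oas3, a sensor of double-stranded RNA, stood at 27.4 ± 11 against 6.23 ± 1.19 CPM, and Xaf1, a pro-apoptotic interferon target, at 43.7 ± 15.6 against 9.15 ± 2.33 CPM. The antiviral GTPase Mx1 stood at 172 ± 55.4 against 51 ± 20.2 CPM. Markers of B cells and neutrophils were also positive in 18 of 18 and 10 of 11 members, with medians of 2.03 and 2.74. Without PanIN 2 these medians were 0.37 and 1.75. Within the title code shared by 3 libraries, with no replicates, they were 0.49 and 0.09, with 14 of 18 and 6 of 11 members positive.

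Over all genes none of these passed. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 24133 genes for PanIN against Healthy, with 2527 at an unadjusted p under 0.05 (1163 higher, 1364 lower) and a smallest adjusted p of 0.236. DESeq2 called 196 genes, 172 higher and 24 lower, and edgeR with no filter on low counts 123, 108 higher and 15 lower. Limma-voom with sample quality weights called 3409, 1395 higher and 2014 lower. Its weights were 4.32 for Healthy 1 and 3.81 for PanIN 2, against 0.17 and 0.27 for Healthy 2 and Healthy 3. The voom count therefore leaned on Healthy 1 and PanIN 2. The 3 libraries of each group lay apart in 12.2% of genes, where chance gives 10%. By edgeR, Xaf1 (ENSMUSG00000040483, GRCm38 chromosome 11, 72301629 to 72313733) had a log2 fold change of 2.26 (SE 0.31, adjusted p = 0.236). Oas3 (chromosome 5, 120753098 to 120777661) had 2.14 (SE 0.35) and Isg15 (chromosome 4, 156199424 to 156200818) 1.54 (SE 0.25), both at adjusted p = 0.238, as had Zc3h7a, a zinc finger gene, with 1.82 (SE 0.29). The lowest p-values among genes lower in PanIN belonged to Gp2 (log2 fold change -1.94), Ctse (-4.25), Glul (-0.95), Jakmip2 (-1.78) and Asph (-0.86). None of these passed in the edgeR fit with the default filter on low counts. Ctse, an aspartic protease, stood at 209 and 77.9 CPM in Healthy 2 and Healthy 3 but at 6.13 CPM in Healthy 1.

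The interferon list was also called by camera with its preset correlation (adjusted p = 3.54e-42), and not with an estimated one (adjusted p = 0.259 with an estimated correlation) or by fry (adjusted p = 0.111). Its mean log2 CPM was 3.91 ± 0.30 in Healthy, 5.17 ± 0.43 in PanIN and 4.36 ± 0.04 in Tumor (SD, n = 3). An exact permutation test over the 1680 assignments of the libraries to 3 groups gave p = 0.00357, the smallest it can give, and 0.146 after adjustment over the 41 lists. One title code was shared by 3 libraries, 1 per group: within it the list's median difference between PanIN and Healthy was 0.66, with 40 of 42 members positive and no replicates, and among the other 6 libraries it was 1.43 with 42 positive.

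Other lists gave few genes in PanIN against Healthy when adjusted over the list alone. In the interferon gamma list 2 of 29 members rose, Nlrc5 (log2 fold change 1.51), a regulator of MHC class I genes, and Ifi47 (1.07). Socs3, a feedback inhibitor of cytokine signalling, rose in the IL-6, JAK and STAT3 list of 28 genes and in the list of 23 regulatory and checkpoint genes (log2 fold change 1.21, SE 0.26). These counts moved with 1 library left out: the interferon gamma list gave 8 without Healthy 1, 7 without Healthy 2, 1 without PanIN 1 and 0 without Healthy 3, PanIN 2, PanIN 3 or Tumor 1. The IL-6 list gave 8 without Healthy 1, the regulatory list 3 without Healthy 1 or Healthy 2, and both gave 0 without PanIN 2 or PanIN 3. The maturation list had 28 of 30 members positive with a median of 0.61, and 0 passed over the list alone by edgeR, with 3 at an unadjusted p under 0.05. Without Healthy 1 the median was 1.26 and 10 members passed, and without Healthy 2 the median was 0.26. The NF-kB and TNF list gave 0 of 30 members by edgeR, with 4 at an unadjusted p under 0.05, and 15 without Healthy 1. Cd40 stood at 147 ± 39.1 CPM against 98.3 ± 36.3, and Cd274, which encodes PD-L1, at 91.7 ± 14.7 against 42.5 ± 22.4 (SD, n = 3). Camera with its preset correlation called 16 of the 41 lists, 13 higher and 3 lower, and 0 with an estimated correlation (smallest adjusted p = 0.259 with an estimated correlation).

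**Figure D2:**
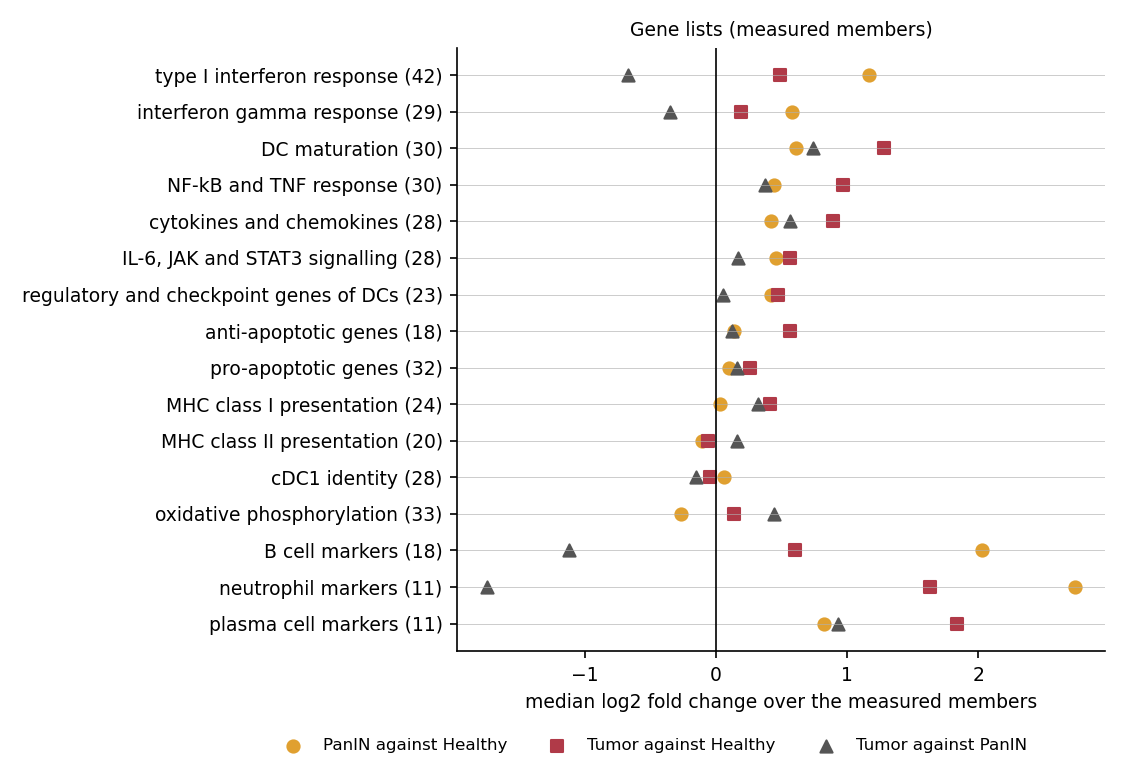
Median log2 fold change over the measured members of 16 gene lists (numbers of members in parentheses) in the 3 comparisons; points carry no error. The type I interferon list has medians of 1.17, 0.49 and -0.67, and the maturation list 0.61, 1.28 and 0.74, for PanIN against Healthy, Tumor against Healthy and Tumor against PanIN.

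Tumor against Healthy asked the same where the node drained a tumor. Genes of dendritic cell maturation equip the cell to activate T cells. All 30 measured members had a positive log2 fold change, with a median of 1.28; 11 rose when adjusted over the list alone and 19 did not pass. Camera called the list with its preset correlation, and not with an estimated one (adjusted p = 0.271 with an estimated correlation), and fry did not call it (adjusted p = 0.124). Tnfsf9, a ligand that costimulates T cells, stood at 14.5 ± 4.19 CPM (SD, n = 3) against 3.06 ± 1.32. Ccl17, a chemokine that attracts T cells, stood at 61.1 ± 38.9 against 10.8 ± 5.22 CPM. The costimulatory receptor Cd40 stood at 226 ± 42.1 against 98.3 ± 36.3 CPM, and Cd80 and Cd83 also rose, with log2 fold changes of 1 and 1.25. Ccr7 and Fscn1 were not among the 11, at log2 fold changes of 1.6 (SE 0.77) and 1.5 (SE 0.78), and Cd86 was at 0.24 (SE 0.34). Plasma cell and epithelial markers were also positive in 11 of 11 and 11 of 12 members, with medians of 1.84 and 2.14. Without Tumor 1 these medians were 0.94 and 0.05.

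In the NF-kB and TNF list 12 of 30 members rose over the list alone, with a median of 0.97 over the list (adjusted p = 0.271 with an estimated correlation). They included Il1b, an inflammatory cytokine (log2 fold change 1.70), Map3k8 (1.73), Nfkbib (1.16) and Cd40, which the maturation list also holds. Il1b stood at 61.6 ± 9.29 CPM against 18.9 ± 8.17 (SD, n = 3). In the list of 28 cytokines and chemokines 3 rose, Il1b, Ccl17 and Cxcl16. In the regulatory and checkpoint list 3 of 23 rose, Cd274 (log2 fold change 1.92), Socs3 (1.27) and Cd200 (0.95). Socs3, Bcl3 (1.33) and Pias3 (1.39) rose among the 28 genes of IL-6, JAK and STAT3 signalling, while Stat3 was at 0.50 (SE 0.26) and Il6ra at -0.72 (SE 0.36). The type I interferon list had a median of 0.49 and 8 members that rose over the list alone, with Isg15 at 42.3 ± 3.84 against 15 ± 4.33 CPM (log2 fold change 1.5). Among 18 anti-apoptotic genes, Bcl2a1b (1.12) and Bcl2a1d (0.90) rose; these near-identical paralogs share reads, so their values are uncertain. With 1 library left out, the regulatory list gave 2 to 8 members higher, the IL-6 list 1 to 11, the cytokines 2 to 7 and the anti-apoptotic genes 0 to 8, each highest without Healthy 1. The regulatory count was also 6 without Healthy 2, and 2 without Healthy 3, PanIN 2, Tumor 1 or Tumor 3. The IL-6 count was 1 without Tumor 3, 2 without Healthy 3, 5 without Healthy 2 and 6 without Tumor 2. The cytokine count was 5 without Tumor 2 and 2 without Healthy 2, Healthy 3, PanIN 2, Tumor 1 or Tumor 3. The anti-apoptotic count was 4 without Tumor 2 and 0 without Healthy 2, Healthy 3, PanIN 2, Tumor 1 or Tumor 3.

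Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6 of 24133 genes, 4 higher and 2 lower, with 4292 at an unadjusted p under 0.05. The larger sets leaned the other way, with 1647 higher and 2645 lower at an unadjusted p under 0.05, 583 higher and 1024 lower by DESeq2, and 496 higher and 1681 lower by edgeR without Healthy 2. Ifitm2, an interferon-inducible membrane protein that restricts virus entry (ENSMUSG00000060591, chromosome 7, 140954837 to 140955987), rose from 17.1 ± 1.01 to 84 ± 21.9 CPM (SD, n = 3; log2 fold change 2.29, SE 0.27, adjusted p = 0.0133). Its call by edgeR with Benjamini-Hochberg adjustment was lost without Healthy 3 (adjusted p = 0.0517), Tumor 1 (0.071) or Tumor 2 (0.0612), without both Healthy 2 and Healthy 3 (0.183) and on counts rebuilt from TPM (0.124), in a range of 2.81e-11 to 0.183 over the alternatives. In Ifitm2, 55.5% of the 31-base words of its longest transcript also occur in other genes. Ugt1a9 (chromosome 1, 88070800 to 88218997), a glucuronosyltransferase, was at 0 counts in all Healthy libraries and was at least 659-fold higher in Tumor, against a floor of 3 counts over the group (adjusted p = 0.0143). Its call by edgeR with Benjamini-Hochberg adjustment was lost without Healthy 3 (adjusted p = 0.0809), Tumor 1 (0.071) or Tumor 2 (0.0612), without both Healthy 2 and Healthy 3 (0.105), at 50 counts in 3 libraries (0.0692), with a surrogate variable (0.0713), on counts rebuilt from TPM (0.211) and on protein-coding genes alone (0.0519), in a range of 3.69e-15 to 0.211. The pseudogene Pgam1-ps2 (chromosome 7, 27469771 to 27470535) was at 0 counts in all Tumor libraries and at least 848-fold lower than in Healthy (adjusted p = 0.00386), a call lost on counts rebuilt from TPM (adjusted p = 0.0766). The other 3 called genes, Zfp781 (at least 134-fold lower), Igkv8-21 and Gm26669, lay outside the rule for named genes and were chosen after their values were seen. Igkv8-21 and Gm26669 were not called without Healthy 3, Tumor 1 or Tumor 2, and Zfp781 was not called with only the 6 libraries compared, without both Healthy 2 and Healthy 3 or on counts rebuilt from TPM. Pgam1-ps2 and Zfp781 share 100% and 97.7% of these words with other genes, and Ugt1a9 67.8%, so their counts are uncertain. The floors cover counting error only.

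The number of genes called rested on the Healthy libraries and on the tool. Without Healthy 2, edgeR called 2177 genes, without Healthy 1 it called 42, and DESeq2 on all libraries called 1607. Camera with its preset correlation called 16 lists, 15 of them higher, and 0 with an estimated correlation. The maturation members that rose over the list alone numbered 2 without Healthy 3 or Tumor 1, 6 without Tumor 3, 18 without PanIN 3 and 26 without Healthy 1; the NF-kB and TNF members numbered 6, 2, 1, 7 and 24 without Healthy 2, Healthy 3, Tumor 1, Tumor 3 and Healthy 1, and the interferon members 14 without Healthy 2, 4 without Healthy 1 and 1 without Healthy 3, Tumor 1 or Tumor 3. Without both Healthy 2 and Healthy 3, a setting chosen after seeing the data, the maturation members numbered 3 and the NF-kB and TNF members 0 by edgeR. Within the shared title code the maturation list's median difference between Tumor and Healthy was 0.93, with 30 of 30 members positive and no replicates, and among the other 6 libraries it was 2.01.

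Tumor against PanIN set the later stage against the earlier one. In the type I interferon list 40 of 42 members had a negative log2 fold change, with a median of -0.67, and 14 fell when adjusted over the list alone. Camera called the list with its preset correlation and not with an estimated one (adjusted p = 0.544 with an estimated correlation). Ifi203, a nucleic acid sensor, stood at 33.8 ± 5.6 CPM (SD, n = 3) against 96.8 ± 40.6 in PanIN, Oas3 at 9.58 ± 1.44 against 27.4 ± 11, and Ifit3, an inhibitor of viral translation, at 2.46 ± 0.36 against 10.4 ± 5.99. Isg15 stood at 42.3 ± 3.84 against 43.6 ± 4.67 CPM. B cell markers were also negative in 17 of 18 members, with a median of -1.12, and neutrophil markers in 10 of 11, with a median of -1.75. Within the shared title code, with no replicates, both directions reversed, with medians of 0.40 and 3.41 and 16 of 18 and 9 of 11 members positive. Among the other 6 libraries the medians were -1.5 and -3.61, with 0 positive. With 1 library left out the B cell median ranged from -1.49 to 0.09. In these 2 lists 0 passed over the list alone by edgeR, with 6 and 3 lower at an unadjusted p under 0.05. Camera called both with its preset correlation (adjusted p = 0.000338 and 0.0079), and neither with an estimated one (adjusted p = 0.586 with an estimated correlation for both). Without PanIN 3, 8 B cell markers fell over the list alone, and 5 neutrophil markers fell without PanIN 1 and 3 without Healthy 1 or Healthy 2. Epithelial markers were positive in 12 of 12 members, with a median of 1.83, which rested on Tumor 1. Without Tumor 1 the median was -0.25, and among the 6 libraries outside the shared title code it was -0.06, with 6 of 12 positive. Ccl17 (log2 fold change 1.88) and Il1b (1.12) rose over their list of 28 cytokines and chemokines alone, where 0 passed by edgeR without PanIN 2, PanIN 3 or Tumor 1 and 1 without Tumor 2. The maturation list had all 30 members positive with a median of 0.74, and 0 passed over the list alone by edgeR, with 5 at an unadjusted p under 0.05.

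By edgeR with Benjamini-Hochberg adjustment 3 of 24133 genes passed, and DESeq2 called 30. By edgeR 1095 genes (4.5%) had an unadjusted p under 0.05, less than this threshold gives when no gene differs. The 3 libraries of each group lay apart in 15.6% of genes, where chance gives 10%. Ugt1a9 was at least 512-fold higher in Tumor (adjusted p = 0.0282), Pgam1-ps2 at least 527-fold lower (adjusted p = 0.00684) and Zfp781 at least 46-fold lower (adjusted p = 0.0282). With 1 library left out, Ugt1a9 lost its call by edgeR with Benjamini-Hochberg adjustment without PanIN 2 (adjusted p = 0.0793), PanIN 3 (0.0812), Tumor 1 (0.115) or Tumor 2 (0.14). It also lost it with a term for the shared title code (adjusted p = 0.105), at 50 counts in 3 libraries (0.117), with only the 6 libraries compared (0.0583), with a surrogate variable (0.0989), on protein-coding genes alone (0.089), with the 7SL term (0.0664) and on counts rebuilt from TPM (0.727), all by edgeR. By limma it lost it with voom and sample weights (adjusted p = 0.0925) and on log2(TPM + 1) (0.0703), in a range of 3.68e-14 to 0.727 over all alternatives. Pgam1-ps2 kept its call with the title code term (adjusted p = 0.000761 by edgeR) and lost it with only the 6 libraries compared (0.0583), by voom (0.0956), on log2(TPM + 1) (0.0762) and on counts rebuilt from TPM (0.18), in a range of 1.24e-14 to 0.18. Zfp781 was not called with the title code term, and of the fits with 1 library left out it was called only in the one without Healthy 2. Camera called 22 lists with its preset correlation and 0 with an estimated one. Without PanIN 2 or without Tumor 3, 0 interferon genes passed over the list alone by edgeR; without PanIN 3 or Tumor 1, 1 did, and without Tumor 2, 5 did.

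Any difference among the 3 stages was called by edgeR with Benjamini-Hochberg adjustment in 5 genes, with 3230 at an unadjusted p under 0.05. The PanIN and Tumor changes against Healthy correlated across genes at 0.65, where simulated unchanged groups sharing simulated controls gave 0.50 in 20 simulations. The covariance was 0.84 against a simulated 0.41, a difference of 0.43. At an unadjusted p under 0.05, 686 genes were higher in both comparisons, where simulation gave 176 and independent lists 79, and 1069 were lower in both, where these gave 79 and 149. The simulations drew genes independently and gave every group the same dispersion per gene. For the maturation list mean the real Healthy libraries were more spread, with an SD of 1.2 against 0.47 in PanIN and 0.43 in Tumor. The simulated values are therefore not a full baseline. The 3 Healthy libraries could also not be split into parts of at least 2 libraries, so part or all of the excess may come from the shared controls. Genes are not independent replicates.

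Markers of other cell types moved with the groups in part. In the B cell list 6 of 18 members rose in PanIN against Healthy over the list alone, with Cd79a at 5.43, 51.6 and 2.69 CPM in the PanIN libraries and 2.4 ± 0.853 in Healthy (SD, n = 3). This count was 14 without PanIN 3, 9 without PanIN 1, and 0 by edgeR without PanIN 2 or any 1 Healthy library. In Tumor against Healthy 13 of 18 were positive with a median of 0.60 and 1 rose, Igkc (log2 fold change 3.47), which did not pass without Healthy 2, Healthy 3 or Tumor 1. In the neutrophil list 4 of 11 rose, with S100a9 at 12 and 7.77 CPM in PanIN 2 and PanIN 3 but 0.081 in PanIN 1; 8 rose without PanIN 1, 7 without Tumor 1 or Tumor 2, 2 without Healthy 1 and 1 without Healthy 3. In the plasma cell list 1 of 11 members rose in PanIN and 3 in Tumor, with Mzb1 at 34.5, 11.9 and 0.835 CPM in the Tumor libraries. The Tumor count was 7 without Healthy 2, 5 without Tumor 3 and 2 without Healthy 1, Healthy 3 or Tumor 1, and the PanIN count 4 without Tumor 3 and 0 without Healthy 2, Healthy 3 or PanIN 1. In the epithelial list 1 of 12 rose in Tumor, Krt7, and Krt8 stood at 23.1 CPM in Tumor 1 alone of the 9 libraries, with at most 1.71 in the others. The epithelial count was 10 without Tumor 2, 9 without Tumor 3, 7 without PanIN 1, 6 without PanIN 2, and 0 by edgeR without Tumor 1, Healthy 2, Healthy 3 or PanIN 3. The acinar and endocrine pancreas list of 17 measured genes gave 2 members that rose, Ctrb1 and Try5, and 1 that fell, Gp2, in PanIN against Healthy. Without PanIN 1, 1 rose, and without Tumor 2 or Tumor 3, 4 and 5 did; without Healthy 2, 3 rose and 2 fell. In Tumor against PanIN Gp2 rose and Ctrb1 and Cel fell, where 4, 6 and 5 fell without Healthy 1, Healthy 2 and Healthy 3. Ctrb1, a digestive protease, stood at 6.21, 3.67 and 1.11 CPM in PanIN and 0.108 ± 0.139 in Healthy. In the fibroblast list all 19 members were negative in PanIN against Healthy, with a median of -0.90, and 0 passed by edgeR, with 2 lower at an unadjusted p under 0.05. With 1 library left out the median ranged from -1.18 to -0.18. Camera called this list with its preset correlation (adjusted p = 0.00122) and not with an estimated one (adjusted p = 0.786 with an estimated correlation), and without Healthy 2, 3 members fell. In the macrophage and monocyte list 1 member fell in Tumor against Healthy, Ccr2 (log2 fold change -1.56), where 2 fell without Healthy 3 and 0 fell by edgeR without Healthy 2, PanIN 2, PanIN 3, Tumor 1 or Tumor 3.

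Single members passed over their list alone in the remaining lists with any call. In Tumor against Healthy these were Rps27l among p53 targets (log2 fold change 1.08), Ndrg1 among hypoxia genes (1.31), Aldoc among glycolysis genes (-1.15) and Fasn among genes of lipid uptake and storage (-1.05). In Tumor against PanIN, mt-Nd3 rose among the 13 mitochondrially encoded genes (0.87) and Rps27l among p53 targets (0.98), the latter lost without Healthy 1 or any 1 PanIN or Tumor library. In Tumor against Healthy with 1 library left out, 0 p53 targets passed without Healthy 3, Tumor 1 or Tumor 2, and 0 glycolysis genes without Healthy 3 or any 1 Tumor library. In the lipid list 0 passed without PanIN 2, PanIN 3 or any 1 Tumor library, and among mitochondrial genes in Tumor against PanIN 0 without any 1 PanIN library, Tumor 1 or Tumor 2, all by edgeR. Other fits gave more: 5 p53 targets and 2 hypoxia genes rose without Healthy 1, and without Healthy 2, 2 p53 targets rose and 1 fell, 1 glycolysis gene rose and 4 fell, and 1 lipid gene rose and 5 fell. Without Healthy 2, 5 mitochondrial genes rose in Tumor against PanIN, and without Healthy 3 or Tumor 3, 2 did. Ddx3y and Eif2s3y rose among the 5 sex-linked genes in both comparisons with Healthy. In Tumor against Healthy, 1 of the 5 passed without Healthy 2, PanIN 1, PanIN 2 or Tumor 1 and 0 by edgeR without Healthy 3 or Tumor 2, and in PanIN against Healthy 0 passed without both Healthy 2 and Healthy 3. In 21 lists 0 members passed over the list alone in any comparison by edgeR: cDC1 identity, MHC class I and class II presentation, pro-apoptotic genes, pattern recognition receptors, immediate early genes, heat shock genes, the unfolded protein response, both cell cycle lists, oxidative phosphorylation, cholesterol biosynthesis, TGF-beta response, cytosolic ribosomal proteins, and markers of T cells, NK cells, cDC2, plasmacytoid dendritic cells, fibroblasts, endothelium and erythroid cells. At an unadjusted p under 0.05, 0 to 10 members per list were higher over the 3 comparisons together, where a member can count more than once. Lower members at this p numbered at most 3 per list and comparison. This was reached by fibroblast markers in Tumor against Healthy and pattern recognition receptors in Tumor against PanIN. The 0 did not hold in every fit with 1 library left out. Without Healthy 2, 11 oxidative phosphorylation genes rose in Tumor against PanIN, and in Tumor against Healthy 9 pro-apoptotic genes rose and 5 fibroblast markers fell; without Healthy 1, 5 immediate early genes rose in Tumor against Healthy. No other of these lists gave over 3 members in one direction in such a fit. The apoptosis genes Bcl2 and Mcl1 had log2 fold changes of 0.08 and 0.44 in Tumor against Healthy, and Bcl2l11 0.63, none of which passed.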

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

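Gene counts depended strongly on the tool, the filter and the Healthy libraries, while the type I interferon list's median in PanIN against Healthy stayed between 0.99 and 1.44 under every alternative run for lists. Counts are given below for PanIN against Healthy, Tumor against Healthy, Tumor against PanIN and any stage, where edgeR gave 0, 6, 3 and 5. DESeq2 gave 196, 1607, 30 and 1043, and no filter gave 123, 1041, 33 and 855. Voom with sample weights gave 3409, 1986 and 3248 for the first, second and any-stage tests. Its weights were 4.32 for Healthy 1, 3.81 for PanIN 2, 0.17 for Healthy 2, 0.27 for Healthy 3, and 0.79 to 1.34 for the others. Requiring 50 counts in 3 libraries gave 3 for Tumor against Healthy and 1 for Tumor against PanIN, and only the 6 libraries compared gave 0 for Tumor against PanIN. The title code term gave 1 for Tumor against PanIN and 3 for any stage. TPM with a pseudocount of 1 gave 4 for PanIN against Healthy and 8 for any stage, and with 0.1 it gave 3 for PanIN against Healthy. Counts rebuilt from TPM gave 1, 1, 0 and 0, and a surrogate variable gave 1 for PanIN against Healthy and 1 for Tumor against PanIN. Of the alternatives chosen after seeing the data, leaving out Healthy 2 and 3 gave 3 for PanIN against Healthy, and protein-coding genes alone gave 2, 0 and 3 for the last 3 tests. The Ccr7 and Fscn1 term gave 2, 1551 and 700 for the first, second and any-stage tests, and the 7SL term gave 520 for Tumor against Healthy and 10 for any stage. Leaving out each library gave 0 to 6, 2 to 2177, 1 to 7 and 0 to 1360, with each highest value but the one for Tumor against PanIN coming without Healthy 2. The cause was not tested, except that fewer libraries or genes entered some fits. The correlation of the PanIN and Tumor changes was 0.56 with no filter, 0.66 on TPM and 0.53 to 0.73 with each library left out.

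Of the 41 lists, camera called 16, 16 and 22 with its preset correlation, 0, 0 and 0 with an estimated correlation, and fry called 0, 0 and 0. On TPM 10 lists were called for Tumor against PanIN. Leaving out each library gave 16 to 21, 12 to 23 and 17 to 23. The maturation list's median in PanIN against Healthy was -0.07 without Healthy 2 and 3, and in Tumor against Healthy it stayed between 0.29 and 2.57. Among the named genes, 0 changed direction while called; calls were gained in 89, 291 and 21 values for the 3 comparisons and lost in 14 for Tumor against Healthy and 17 for Tumor against PanIN. Ifitm2 kept a log2 fold change of 2.15 to 2.49. A term for sex was not run, because Y-linked genes were present in all 9 libraries and Xist stood at 57.8 CPM or more in 8 of them, with 4.13 in Tumor 2. A graded term for these genes was not run either. No paired analysis was possible because the labels carry no replicate numbers. The 1 title code that groups share, with 1 library in each, entered as the term above. Each other code belonged to 1 library. In ascending order these codes ran through Tumor, then PanIN, then Healthy. Outside the shared code their order therefore cannot be told apart from stage, and the term does not adjust for it. Depth limits the genes at 0 to floors of 3 counts over a group.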

Other observations

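The tests with terms for 7SL RNA and for Ccr7 and Fscn1, the one without Healthy 2 and the one over choices of 3 libraries were chosen after the results they bear on were seen. For Tumor against PanIN, 31 of 33 oxidative phosphorylation genes had positive log2 fold changes with a median of 0.44, and 37 of 38 cytosolic ribosomal protein genes with a median of 0.44. Camera called both with its preset correlation (adjusted p = 2.9e-13 and 5.01e-12), and neither with an estimated one (adjusted p = 0.579 and 0.586 with an estimated correlation). By edgeR, 0 members of either list passed over the list alone, with 8 and 1 higher at an unadjusted p under 0.05; without Healthy 2, 11 oxidative phosphorylation genes passed. All 13 mitochondrially encoded genes were also positive, with a median of 0.66 (camera adjusted p = 2.9e-13 with its preset correlation, adjusted p = 0.544 with an estimated correlation). Cpne8, a calcium-binding protein, stood at 27.3 ± 5.59 CPM (SD, n = 3) in Tumor, 8.25 ± 1.88 in PanIN and 11.5 ± 0.291 in Healthy. It did not pass in the edgeR fit with the default filter on low counts and Benjamini-Hochberg adjustment (adjusted p = 0.167), and this call depended on the filter and the tool.

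The first pattern was the higher type I interferon list in PanIN. A term for 7SL RNA left the list's median at 1 (95% bootstrap interval 0.79 to 1.25), and a term for the B cell markers at 1 (0.83 to 1.42). With a term for Ccr7 and Fscn1 it was 1.31 (1.07 to 1.68). Each interval lay above 0.59, the bound set for the test, so the estimated rise remained with each term. These intervals resample genes, which are not independent, and hold no spread between libraries. The tests therefore cannot exclude RNA composition, B cell RNA or the share of mature cells as a cause. A response of the cells to interferon in PanIN-draining nodes is one candidate explanation. The mean log2 CPM of the 5 sex-linked genes also lay higher in PanIN (5.22, 5.52 and 5.68) than in Healthy (4.93, 4.34 and 4.32). These are Xist and Y-linked genes, which a shift in the sex mix would move in opposite directions. All 5 had a positive log2 fold change, so this mean does not measure the sex mix. Neutrophil RNA, the sex mix of the libraries, the order of the title codes, the animals and other handling differences stay open as untested.

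The second pattern was the higher maturation list in Tumor. Without Healthy 2 the median was 0.96 (95% bootstrap interval 0.76 to 1.06, above 0.64), so the estimated rise remained without this library. With the 7SL term the median was 2.57 (2.03 to 3.35). These intervals also resample genes and hold no spread between libraries. They therefore cannot exclude Healthy 2 or RNA composition as a cause. With the Ccr7 and Fscn1 term the median over the other 28 members was 0.31 (0.20 to 0.60, below 0.62), as a different share of mature cells would give. More maturation in each cell would lower this value too, since both genes are maturation markers, so the test does not separate a larger share of mature cells from a stronger state per cell. Either may underlie the pattern. The order of the title codes stays open as untested here too.

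The third pattern was the genes at 0 counts on 1 side. Of the 84 choices of 3 libraries, 1, the Tumor libraries, gave 3 such genes, and the highest other choice gave 2. The lowest share of 31-base words found in other genes was 67.8%, in Ugt1a9, between the bounds set for the test. Shared reads therefore cannot be told apart from a real difference for these genes as a set. For Pgam1-ps2, 100% of the words occur in Pgam1, so its counts rest on how the model split reads. They do not show that its RNA was absent in Tumor. Pgam1, Pgam1-ps1 and Pgam1-ps2 together stood at 214 ± 72.6 CPM (SD, n = 3) in Healthy, 179 ± 23.8 in PanIN and 206 ± 35.9 in Tumor, and all Ugt1a genes at 47.2 ± 16.4, 47.3 ± 6.78 and 52 ± 4.81, sums chosen after the values were seen. Assignment of reads among copies, possibly from strain variants, is a candidate explanation.

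Other splits of the libraries bear on the gene counts. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. For PanIN against Healthy the real value was 0, so all 10 splits gave as many by construction and their number says nothing; the highest other was 1666. For Tumor against Healthy the real value was 6 and the highest other 1, and for Tumor against PanIN 3 and 0, so in each the 1 split as high was the real one. For any stage, 3 of 50 splits gave at least the real value of 5, the real one counted among them and the others at 743 and 755, so chance cannot be excluded. The splits with 1666 and 755 genes called point to a structure of the libraries other than stage. In these and in the split with 743, Healthy 1, Healthy 3 and PanIN 1 stood together. These libraries had the highest shares of 7SL RNA (0.76%, 1.78% and 0.56%) and of mitochondrial ribosomal RNA (1.26%, 2.77% and 1.03%). Only they had negative values on the first principal component (-63.7, -169.2 and -32.2).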
